A study of Homo sapiens with 10 samples.

How the data were processed

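RPMI-8402 cells were profiled by CUT&RUN with antibodies to MYC, MYCN, H3K4me3, H3K27ac and H3K4me1 and with control IgG, per the labels' protocols. Fragments were released with a protein A/G nuclease fusion and sequenced as paired reads, per the labels' protocols. The 10 libraries fall into 4 sets named in the labels, each with an IgG library. Peak lists of 6 libraries were used. IgG lists and signal tracks were not used here.

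The deposited values are peak positions in bases on hg19, per the submitters' processing notes. Each list has 4 columns, namely chromosome, start, end and a name, and holds no score, fold, p or q. The tools named in the submitters' processing notes are MACS2 and SEACR, and versions are not given in the sources used here. The MYCN list holds peaks of all fragments from cutruntools output at a q below 0.01, per the file headers. H3K4me3 peaks were called with MACS2, per the file headers. MYC of set C comes from SEACR in its stringent mode on paired reads, and MYC of set D from MACS2 on reads treated as unpaired, per the file headers. The headers of the 2 MYC lists point to the same signal track, although their peaks differ, and the labels name the MYC library of set D as its own control. Different callers can give different peaks from 1 library, so the 2 lists may not be independent. They were treated as 2 libraries, as labelled. The H3K27ac and H3K4me1 lists carry no header, and their names give the broad and the narrow peak format. Each list belongs to 1 library, and none is described as pooled. The aligner and the handling of duplicates are not given in the sources used here for most lists.

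These differences shape what can be compared. The lists come from different callers and settings, so tests of width were made within a list only. A list length depends on depth, antibody, caller and threshold together, so the number of peaks is not read as the amount of binding. Depth is unknown, because the lists give no read counts.

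Peaks on chromosomes 1 to 22 and X were used. Those on any other sequence, such as chromosome Y or the mitochondrial sequence, were left out. This removed 35 of 9533 regions from MYC of set C, 53 of 18071 from MYC of set D, 1 of 896 from MYCN, 46 of 39574 from H3K27ac, 26 of 39529 from H3K4me1 and none from H3K4me3. Peaks count as overlapping when they share at least 1 bp. Each overlap was compared with 1000 random placements of the first list within its chromosomes, between the first and last peak of any list, with widths kept. The one-sided permutation p cannot go below 0.001. Random placement takes no account of mappability or GC content, and describes chance only. Shares have exact Clopper-Pearson intervals. Shares of marked peaks in 2 groups were compared with Fisher's exact test, two-sided, adjusted by the Benjamini-Hochberg method over the 3 marks. Widths were compared by a two-sided permutation test of ranks with 100000 resamples. Enhancer-like regions are H3K4me1 regions that overlap H3K27ac and no H3K4me3. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

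The overlap code was tested on simulated data. In a simulated list of 1000 peaks set against H3K4me3, 400 overlaps were planted and 400 were recovered. Of 40 random lists, 0 had a p under 0.05. All 30 ordered pairs of the real lists gave the same counts as bedtools 2.31.1.

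The main comparisons, their tests and most alternatives were fixed before the data were examined. The tests of peak and region width, with the trend over deciles, were not in that plan. Nor were the tests of marks at MYC sites shared or not shared between the MYC lists, or at set C regions with and without MYCN. The sorting of peaks into classes of marks, the split of H3K4me3 regions by H3K27ac and the distances around them were also outside it. The rule for regions named in the text took the 10 with the highest scores among MYCN peaks at promoters, MYC set D peaks at promoters shared with set C, and MYCN promoter peaks without MYC, together with the 10 widest H3K4me3 regions joined within 1 kb and the 10 longest H3K27ac clusters joined within 12.5 kb. As the lists hold no score, the rule's tie-break, width, took its place, and overlap with H3K4me3 stood for a promoter. For MYCN promoter peaks without MYC the rule found 8. A gene annotation of hg19 was not used here, so regions are given by coordinates and not by gene. For the same reason the planned comparisons of peak positions relative to genes, of genes with both factors, of gene lists and of E-box sequences were not run, nor was that of peak strength, which needs scores. The alternatives were the overlap rule, random placement within marked regions, MYC from either set alone, the wider peaks of each list, equal numbers of the widest peaks, and a distance of 2 kb from H3K4me3, the last 3 chosen after the data were examined.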

Results

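MYC and MYCN binding and the surrounding histone marks were mapped by CUT&RUN in RPMI-8402, an established human T-cell acute lymphoblastic leukaemia cell line. In CUT&RUN an antibody bound to its target in permeabilised cells recruits a nuclease, which releases the DNA beside the target for sequencing. MYC and MYCN are closely related transcription factors that bind DNA as partners of MAX. H3K4me3 is a histone mark of active promoters, H3K27ac a mark of active promoters and enhancers, and H3K4me1 a mark found mostly at enhancers and at the flanks of promoters. The series held 10 libraries in 4 sets, labelled A to D, of which 4 were control IgG libraries. Peak lists of 6 libraries were analysed here: MYCN in set A, H3K4me3 in set B, MYC, H3K27ac and H3K4me1 in set C, and MYC again in set D. By the labels MYC was therefore the only target with 2 libraries, and every other list stood alone without a replicate. The headers of both MYC lists point to the same signal track, so whether the 2 lists are independent replicates is not settled.

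On the autosomes and chromosome X the MYCN list held 895 peaks with a median width of 222 bp. The MYC list of set C held 9498 regions with a median width of 1165 bp, and that of set D held 18018 peaks with a median width of 422 bp. There were 13852 H3K4me3 regions with a median width of 1341 bp, 39528 H3K27ac regions with a median of 551 bp and 39503 H3K4me1 regions with a median of 324 bp. H3K27ac covered 25.9 Mb, H3K4me3 19.7 Mb, H3K4me1 15.9 Mb, MYC 12.3 Mb in set C and 8.75 Mb in set D, and MYCN 0.242 Mb. The lists give positions only, with no read count or score, so the depth of each library is unknown and no interval for depth is given. Binomial intervals below are exact 95% intervals and cover counting error over the listed peaks only. Peaks are not replicates, so the p-values describe these lists and not the spread between cultures.

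The first comparison asked how far the MYC lists of the 2 sets named the same places. Of the MYC regions of set C, 82.5% (95% interval 81.8 to 83.3%, 7839 of 9498) overlapped a MYC peak of set D, and 45.1% of the set D peaks (44.3 to 45.8%, 8119 of 18018) overlapped a region of set C. Random placement on the same chromosomes gave 1.32% and 0.704%, and none of 1000 placements reached the observed values (one-sided permutation p = 0.001 for each direction, the smallest possible). Placement restricted to regions with any of the 3 histone marks gave 39.5% and 23.7%, so that the excess over chance was far smaller there (one-sided permutation p = 0.001 for each direction). The lists shared 4.66 Mb, which was 37.9% of the bases of set C and 53.3% of those of set D, with a Jaccard index of 0.285. The MYC sites found in both sets were mostly at promoter-like chromatin. H3K4me3 overlapped 74.1% of the set C regions shared with set D against 26.8% of the 1659 regions absent from set D (Fisher's exact test, two-sided, adjusted p = 4.62e-285). Of those 1659 regions, 30.8% (28.6 to 33.1%) overlapped none of the 3 marks, compared with 3.29% (2.91 to 3.71%) of the shared ones. Among set D peaks, H3K4me3 overlapped 73.3% of the 8119 shared ones and 41.8% of the 9899 absent from set C, while H3K4me1 overlapped 21.0% and 34.1% (Fisher's exact test, two-sided, adjusted p = 2.69e-86 for H3K4me1). The 2 lists came from different peak callers, so set and caller cannot be told apart in these differences. Their headers point to the same signal track, so the overlap cannot be read as agreement between independent replicates. With only the 895 widest peaks of each list, a setting added after the data were examined, 25.1% of either list overlapped the other, against 0.150% and 0.151% at random (one-sided permutation p = 0.001).

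The second comparison placed MYCN against MYC. Nearly every MYCN peak lay in a MYC peak: 882 of 895 (98.5%, interval 97.5 to 99.2%) overlapped MYC in at least 1 of the 2 sets. MYC of set D covered 879 MYCN peaks (98.2%, 97.1 to 99.0%), MYC of set C covered 637 (71.2%, 68.1 to 74.1%), and 634 (70.8%) lay in both. Random placement gave 0.870% for either set (one-sided permutation p = 0.001, the smallest possible), and placement restricted to regions with any of the 3 histone marks gave 32.1% (one-sided permutation p = 0.001). The reverse overlap was small, since MYCN was found at 6.51% of the MYC regions of set C (6.02 to 7.02%) and 4.72% of the MYC peaks of set D (4.41 to 5.04%). When only the 895 widest peaks of each factor list were kept, a setting added after the data were examined, 23.7% of MYCN peaks lay in MYC of either set, still above the 0.145% of random placement (one-sided permutation p = 0.001).

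**Figure D1:**
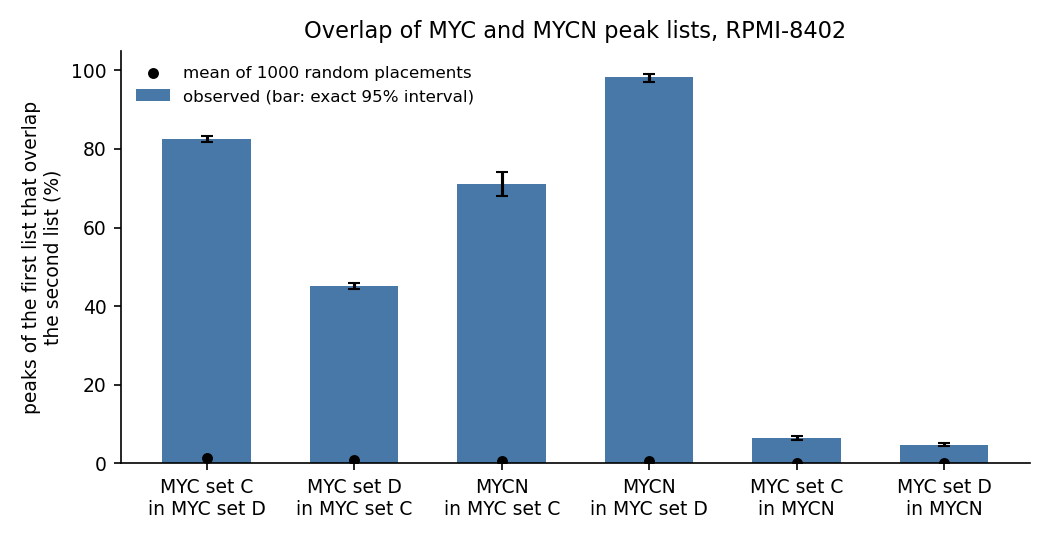
Bars give the percent of peaks of the first list that overlap the second list by at least 1 bp, for each ordered pair of the MYC set C, MYC set D and MYCN lists, with exact 95% intervals as error bars and black points for the mean of 1000 random placements. MYCN lies in MYC set D for 98.2% of its peaks, while 4.72% of MYC set D peaks hold MYCN.

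MYC peaks that held MYCN were wider than those that did not. In set D the median width was 741.5 bp (quartiles 585.25 and 938) at the 850 peaks with MYCN and 409 bp (280 and 598) at the 17168 without it, a ratio of 1.81 (two-sided permutation test of ranks, p = 1e-05, the smallest possible). In set C the medians were 1247.5 bp and 1159.5 bp, a ratio of 1.08 (two-sided permutation test of ranks, p = 1e-05). The share of MYC set D peaks with MYCN rose with every decile of MYC peak width, from 0.278% of the narrowest 1799 peaks to 17.4% of the widest 1805. A wide MYC peak overlaps a MYCN peak more easily, and these comparisons do not take that into account.

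**Figure D2:**
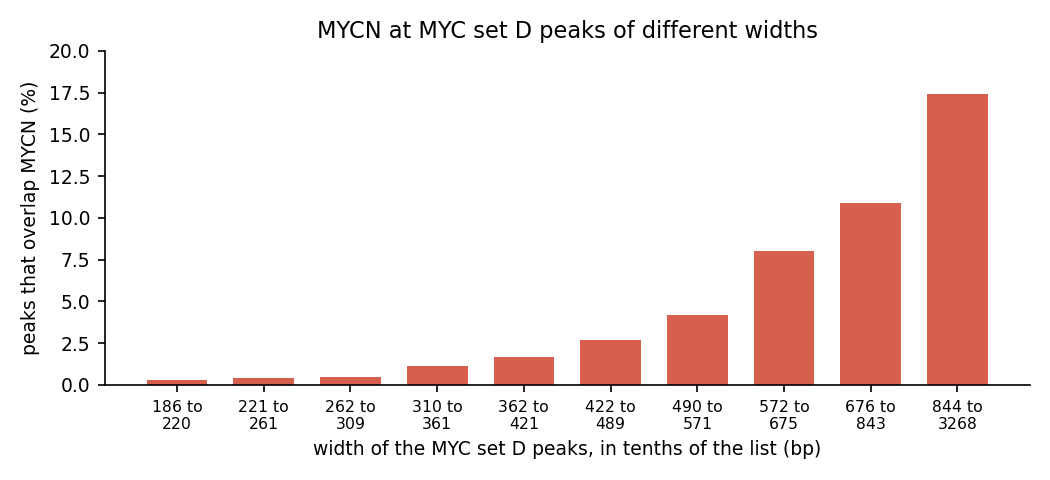
Bars give the percent of MYC set D peaks that overlap a MYCN peak, with the peaks grouped into 10 classes of near-equal size by their width in bp. The share lies at 1.66% in the class of 362 to 421 bp and at 17.4% in the class of 844 to 3268 bp.

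The 10 widest MYCN peaks in H3K4me3 regions were all sites shared with MYC. On hg19 these were chromosome 16 from 4321606 to 4322524 (919 bp), chromosome 1 from 47799472 to 47800373 (902 bp), chromosome 2 from 70313222 to 70314119 (898 bp) and chromosome 1 from 244997978 to 244998866 (889 bp). Next in width were chromosome 2 from 86332728 to 86333587, chromosome 2 from 73511709 to 73512565, chromosome 10 from 32635210 to 32636026 and chromosome 8 from 37888493 to 37889276. The last of the 10 were chromosome 7 from 112031410 to 112032188 and chromosome 10 from 131908861 to 131909581. All 10 overlapped MYC in both sets and H3K27ac, and only the peak on chromosome 7 also overlapped H3K4me1. Among the 10 widest MYC set D peaks in H3K4me3 that set C shared, 5 held MYCN. The widest was on chromosome X from 153236081 to 153238374 (2294 bp) and held no MYCN peak. Next came chromosome 16 from 4321266 to 4323486 (2221 bp), around the widest MYCN peak, then chromosome 19 from 18699553 to 18701591 (2039 bp, with MYCN) and chromosome 17 from 7338577 to 7340533 (1957 bp, with 2 MYCN peaks).

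Taken singly, H3K4me3 and H3K27ac each overlapped most peaks of every factor list. H3K4me3 overlapped 82.2% of MYCN peaks (79.6 to 84.7%), 65.9% of MYC regions of set C (64.9 to 66.8%) and 56.0% of MYC peaks of set D (55.2 to 56.7%). H3K27ac overlapped 80.6% of MYCN peaks (77.8 to 83.1%), 78.2% of MYC in set C (77.4 to 79.0%) and 70.7% in set D (70.0 to 71.3%). H3K4me1 was met less often, at 16.8% of MYCN peaks (14.4 to 19.4%), 26.6% of MYC in set C (25.7 to 27.5%) and 28.2% in set D (27.5 to 28.8%). All 9 overlaps were above random placement on the same chromosomes, which gave between 0.923% and 2.99% (one-sided permutation p = 0.001 for each, the smallest possible). Placement inside marked regions narrowed these gaps. For H3K4me3 the random means were then 41.7% for MYCN, 44.3% for MYC in set C and 42.8% for MYC in set D. For H3K27ac they were 60.6%, 73.5% and 64.2%, so that the MYC shares exceeded chance by little, although every H3K4me3 and H3K27ac share stayed above it (one-sided permutation p = 0.001 for each). H3K4me1 fell below chance, with random means of 38.9%, 47.5% and 41.1%. Among the 895 widest peaks of each list, a setting that changes list length and peak width together, H3K4me3 overlapped 91.1% of MYC in set D and 72.5% of MYC in set C, above and below the MYCN share. Counting only peak centres inside a mark lowered H3K4me1 to 13.7% for MYC in set C, from 26.6%, and among the wider peaks of each list, those at or above its median width, it lay between 9.13% for MYCN and 13.8% for MYC in set C.

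Sorted by the marks they met, 66.7% of MYCN peaks had H3K4me3 with H3K27ac (63.5 to 69.8%), compared with 54.3% of MYC regions of set C (53.3 to 55.3%) and 41.5% of MYC peaks of set D (40.8 to 42.2%). The enhancer-like combination, H3K27ac with H3K4me1 and without H3K4me3, was found at 6.82% of MYCN peaks (5.25 to 8.67%), 12.8% of MYC in set C (12.2 to 13.5%) and 16.6% in set D (16.0 to 17.1%). None of the 3 marks was met by 2.46% of MYCN peaks (1.55 to 3.70%), 8.10% of MYC in set C (7.56 to 8.66%) and 10.5% in set D (10.1 to 11.0%).

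**Figure D3:**
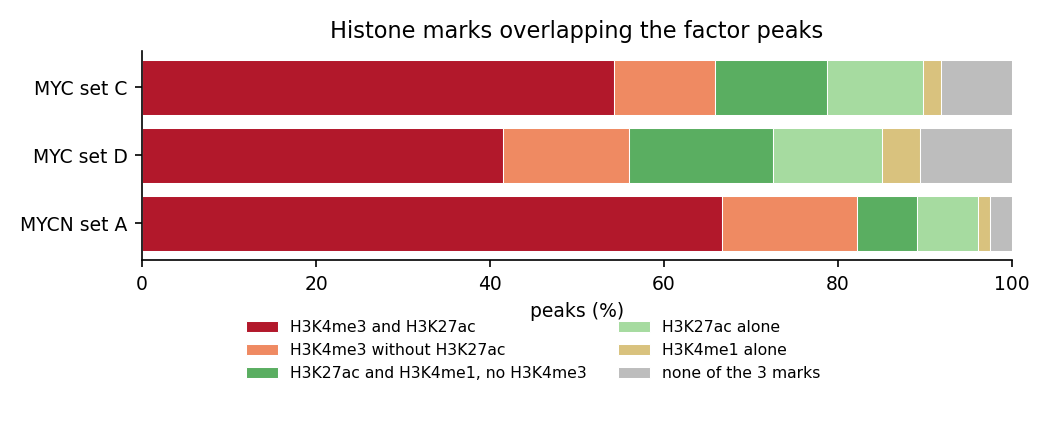
Each horizontal bar splits 1 factor list into 6 classes by the histone marks its peaks overlap, in percent of peaks. H3K4me3 together with H3K27ac takes 54.3% of MYC set C, 41.5% of MYC set D and 66.7% of MYCN.

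MYC peaks with MYCN carried the promoter marks more often than other MYC peaks. In set D, H3K4me3 overlapped 83.6% of the 850 peaks with MYCN and 54.6% of those without, a difference of 29.1 percentage points (Fisher's exact test, two-sided, adjusted p = 1.45e-68). H3K27ac overlapped 88.0% and 69.8% (adjusted p = 1.81e-34, Fisher's exact test), and H3K4me1 20.9% and 28.5% (adjusted p = 9.87e-07, Fisher's exact test). Set C showed the same order, with H3K4me3 at 89.2% of 618 regions with MYCN and 64.2% of 8880 without (Fisher's exact test, two-sided, adjusted p = 1.22e-42). With only the wider peaks of every list kept, marks and MYCN included, the set D differences were 14.8 points for H3K4me3, 10.1 for H3K27ac (18.2 with all peaks) and -3.73 for H3K4me1 (-7.59 with all peaks) (Fisher's exact tests, two-sided, adjusted p = 6.57e-09, 4.47e-05 and 0.0225). In that setting a MYC peak whose MYCN peak was dropped counts as without MYCN, so it is not the same contrast among wide MYC peaks. Peak width was not matched in these tests, although the MYC peaks with MYCN were wider.

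MYCN peaks outside MYC were too few for a firm account. Of the 13 that overlapped MYC in neither set, 5 (38.5%) overlapped H3K27ac, against 81.2% of the 882 others, a difference of 42.7 points (Fisher's exact test, two-sided, adjusted p = 0.00279). H3K4me3 was met by 8 of the 13 (61.5%) against 82.5% (Fisher's exact test, adjusted p = 0.0952), and H3K4me1 by 4 of the 13 (30.8%) against 16.6% (Fisher's exact test, adjusted p = 0.250), and these 2 differences did not pass the test. With MYC taken from set C alone, 258 MYCN peaks lay outside it, but 245 of these lay in MYC of set D. In that contrast the H3K27ac difference was 10.8 points and all 3 marks passed (Fisher's exact test, adjusted p = 0.000369 for H3K27ac). It therefore says little of MYCN outside MYC. The 8 in H3K4me3 were between 158 and 356 bp wide, and the widest of them were on chromosome 19 from 47287960 to 47288315, chromosome 5 from 169064681 to 169064959 and chromosome 5 from 54522521 to 54522737.

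Taken from the side of the marks, MYC was widespread at H3K4me3 regions and much less common at enhancer-like ones. Of the 13852 H3K4me3 regions, 76.7% (76.0 to 77.4%) held MYC in at least 1 set, 43.4% (42.6 to 44.3%) in both, and 5.10% (4.74 to 5.48%) held MYCN. Of the 18564 H3K4me1 regions that overlapped H3K27ac and no H3K4me3, 20.4% (19.9 to 21.0%) held MYC in at least 1 set, 4.44% (4.15 to 4.75%) in both, and 0.339% (0.261 to 0.434%) held MYCN. The difference was 56.3 percentage points for MYC, with an odds ratio of 12.8 and a p of Fisher's exact test too small for the software to represent. For MYCN it was 4.76 points, with an odds ratio of 15.8 (Fisher's exact test, two-sided, p = 1.35e-187). MYC from set C alone gave 39.8 points and MYC from set D alone 55.4 points. The H3K4me3 regions were wider than the H3K4me1 regions, with medians over the whole lists of 1341 and 324 bp, and a wide region overlaps a peak more easily, which enters these differences. Counting only region centres inside factor peaks gave 36.3 points for MYC and 1.16 points for MYCN. Counting by centres also changed which regions were classed as enhancer-like, so that 29279 regions were compared in place of 32416. The smaller differences therefore cannot be assigned to region width alone.

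Acetylation divided the H3K4me3 regions further. With H3K27ac, 88.5% of 9176 H3K4me3 regions held MYC in at least 1 set (87.8 to 89.1%) and 7.02% held MYCN (6.50 to 7.56%). Without H3K27ac, 53.7% of 4676 held MYC (52.3 to 55.1%) and 1.35% held MYCN (1.04 to 1.72%). H3K4me1 regions with neither other mark held MYC in 5.80% of 18892 cases (5.47 to 6.14%) and MYCN in 0.0582% (0.0291 to 0.104%). H3K4me3 regions with a factor were also wider: the median was 1580.5 bp with MYC of set D and 511 bp without, 1687 bp with MYC of set C and 1010 bp without, and 1933 bp with MYCN and 1305 bp without (two-sided permutation tests of ranks, p = 1e-05 each, the smallest possible). Neither the split by H3K27ac nor the rank tests take into account that wide regions overlap peaks more easily.

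**Figure D4:**
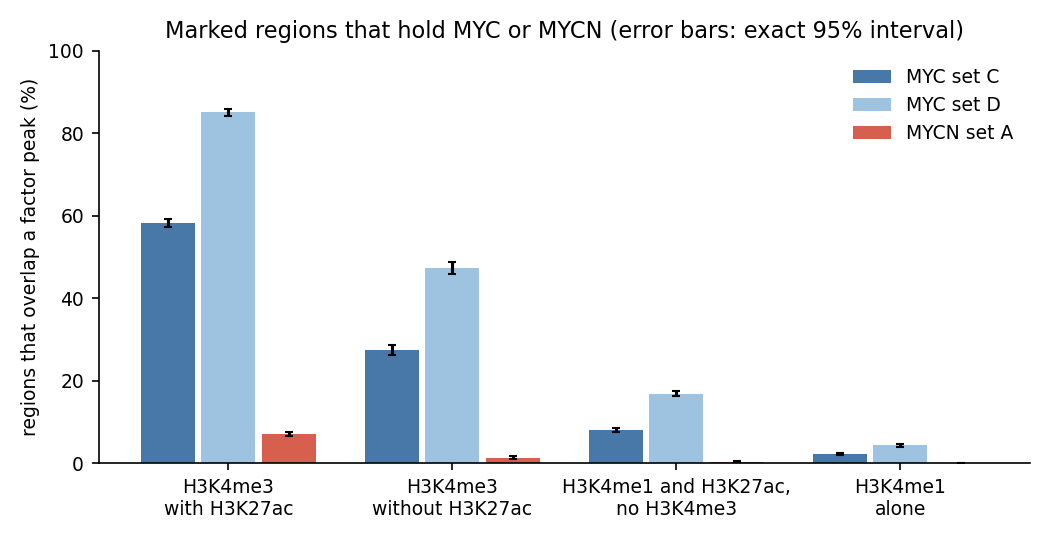
Bars give the percent of regions in 4 classes of histone marks that overlap a MYC set C, MYC set D or MYCN peak, with exact 95% intervals. MYC set D reaches 85.0% at H3K4me3 regions with H3K27ac and 16.9% at H3K4me1 regions with H3K27ac and no H3K4me3.

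The last comparison set the histone marks against each other. H3K27ac overlapped 66.2% of H3K4me3 regions (65.4 to 67.0%) and 50.4% of H3K4me1 regions (49.9 to 50.9%). H3K4me1 overlapped 45.3% of H3K27ac regions (44.8 to 45.8%), and H3K4me3 23.2% (22.7 to 23.6%). H3K4me1 and H3K4me3 were mostly apart, with 14.4% of H3K4me3 regions (13.9 to 15.0%) and 5.18% of H3K4me1 regions (4.97 to 5.41%) overlapping the other mark, and 2.37% of the bases of H3K4me3 shared. Random placement gave at most 3.07% for these pairs (one-sided permutation p = 0.001 for each of the 6 ordered pairs, the smallest possible). With 5 kb added to each side of the H3K4me3 regions the share with H3K4me1 was 41.0%, compared with 13.5% at random, and the ratio to random fell from 5.58 on the regions themselves to 3.02. Counted by the centre of the region, 4.30% of H3K4me3 regions lay in H3K4me1.

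The broadest H3K4me3 domains, joined within 1 kb, were on chromosome 12 from 12867383 to 12880390 (13008 bp), chromosome 7 from 5458036 to 5470163 (12128 bp), chromosome 7 from 92458885 to 92469367 (10483 bp) and chromosome 21 from 36255344 to 36264720 (9377 bp). Of the 10 broadest, 9 held MYC of set C, 8 held MYC of set D and 1 held MYCN, on chromosome 6 from 32934699 to 32942884. MYC of at least 1 set was missing from 2 of them. The domain on chromosome 7 from 50343680 to 50352495 (8816 bp) overlapped 2 H3K27ac regions and no factor peak. That on chromosome 19 from 13206348 to 13214481 held 4 regions of MYC set C and no peak of set D. The longest H3K27ac clusters, joined across the wider gap stated with the processing, were on chromosome 21 from 43051762 to 43203891 (152130 bp), chromosome 12 from 125053645 to 125205611 (151967 bp), chromosome 2 from 43333062 to 43466168 (133107 bp) and chromosome 4 from 87845636 to 87967210 (121575 bp). All 10 of the longest held MYC in both sets. MYCN was found in 1 of them, with 2 peaks on chromosome 21 from 43448877 to 43546379. The clusters on chromosomes 21 and 12 that led the list held 25 and 28 H3K4me1 regions and 1 and 0 H3K4me3 regions, and MYC set D had 5 and 8 peaks in them.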

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

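All tests in this part were chosen after the values were seen. The MYC list of set D held 6 peaks on the mitochondrial sequence, outside the comparisons, where a count above 3 was singled out. The H3K27ac list held 2 there, and the MYC list of set C, MYCN, H3K4me3 and H3K4me1 held 0. No IgG list was used for comparison, so whether the 6 peaks exceed background was not tested.

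The first pattern weighed is that MYCN lay almost wholly inside MYC of set D. Use of the same strong promoters by any factor stays open. Among H3K4me3 regions with H3K27ac, MYC of set D was at 99.7% of the 644 with MYCN. At equal region width it was at 88.5% of those without MYCN, a difference of 11.2 percentage points (two-sided permutation p = 0.0001, the smallest possible). The share of 99.7% largely restates the overlap of MYCN with MYC of set D, so the difference is no separate evidence. Only width was matched, and the lists hold no score for promoter strength. A limit of detection is a candidate explanation for why so few MYC sites held MYCN. The share with MYCN was 10.4 times as high in the widest decile of MYC set D peaks as in the fifth. That ratio restates the width trend given above, and wide peaks overlap MYCN more easily, so it cannot decide. Recognition of MYC sites by the MYCN antibody or by assay background cannot be told apart from binding of both factors, because 16 MYCN peaks outside MYC of set D are too few to decide and no library without MYC or IgG signal was used here. Binding of MYC and MYCN to the same sites in these cells stays open as a hypothesis.

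The second pattern is that set D MYC peaks absent from set C were more often enhancer-like than shared ones, 22.5% against 9.37%. Narrower peaks account for part of it but not all. Weighted to the widths of the unshared peaks, shared peaks were enhancer-like in 13.3% of cases. That left a difference of 9.21 percentage points at equal width (two-sided permutation p = 0.0001, the smallest possible). The same held in the other direction, where set C regions absent from set D were enhancer-like in 19.8% of cases against 11.4% of shared ones, a difference of 8.39 points (Fisher's exact test, two-sided, p = 1.03e-18). The excess was not particular to enhancer-like peaks, since peaks with none of the 3 marks made up 15.0% of the unshared and 5.11% of the shared peaks in set D, and 30.8% and 3.29% in set C. Set and peak caller cannot be told apart as the source, and no biological explanation was tested.

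The third pattern is that H3K4me3 regions held MYC of set C at very different rates on different chromosomes, from 24.2% on chromosome 13 to 59.2% on chromosome 4. Spread here means the root mean square deviation of the chromosome shares from the share over all chromosomes, weighted by the number of regions. For MYC of set C it was 8.70 percentage points, against 3.50 when 5-Mb bins were shuffled (one-sided permutation p = 0.001, the smallest possible). Region width and the presence of an H3K27ac peak do not account for the spread. Regions with H3K27ac and MYC of set D still spread by 8.89 points around the share expected for their widths (one-sided permutation p = 0.001). The amount of H3K27ac could not be matched, because the lists hold no score, so differences in its strength stay open. The density of H3K4me3 regions stays undecided, with a Spearman rho of 0.356 over 23 chromosomes (adjusted permutation p = 0.096, Pearson r = 0.342, adjusted permutation p = 0.11, and r = 0.0739 without the 2 chromosomes farthest from the median density). A property of whole chromosomes, such as DNA copy number, was not measured and is a candidate explanation. MYC of set D ranked the chromosomes similarly (rho = 0.698, adjusted permutation p = 0.000467, r = 0.752, adjusted permutation p = 3.33e-05, r = 0.650 without the 2 farthest). MYCN did so more loosely (rho = 0.495, adjusted permutation p = 0.0213, r = 0.508, adjusted permutation p = 0.0175, r = 0.397 without the 2 farthest). The spreads of MYC of set D and MYCN were small, 2.80 points against 2.18 shuffled (one-sided permutation p = 0.033) and 1.30 against 0.977 (one-sided permutation p = 0.02). The marks of set C also ranked the chromosomes like MYC of set C, with H3K27ac at rho = 0.811 (adjusted permutation p = 5e-05, r = 0.837, adjusted permutation p = 2.5e-05, r = 0.804 without the 2 farthest) and H3K4me1 at rho = 0.760 (adjusted permutation p = 0.0001, r = 0.775, adjusted permutation p = 2.5e-05, r = 0.728 without the 2 farthest), and spread by 5.03 and 5.55 points against 2.78 and 2.64 shuffled (one-sided permutation p = 0.001 each). A bias of the set C libraries therefore cannot be told apart from a property of the cells. Of the lists, 3 come from that set, while MYC of set D and MYCN follow its order only in part and with a smaller spread. The MYC lists of the 2 sets may also share a source, as their headers point to the same signal track. In all, 5 relations were computed.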

How the results depend on the processing

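In all, 28 results were computed again under the alternatives, which gave 99 values, and 90 of them kept their direction and their side of the threshold. The settings of equal numbers of widest peaks, of wider peaks and of 2 kb from H3K4me3 were chosen after the data were examined. Placement inside marked regions reversed the comparison of H3K4me1 with chance for all 3 factor lists, at 26.6% for MYC in set C, 28.2% for MYC in set D and 16.8% for MYCN against random means of 47.5%, 41.1% and 38.9%, and the cause of the reversal was not tested. Among MYCN peaks with and without MYC, the differences in H3K4me3 and H3K4me1 passed the threshold when MYC came from 1 set alone. With set D they were 26.5 and -21.1 percentage points (Fisher's exact tests, adjusted p = 0.0202 and 0.0373). With set C they were 19.2 and -13.5 points (Fisher's exact tests, adjusted p = 2.36e-10 and 4.01e-06). Of the 16 MYCN peaks outside set D, 3 lay in MYC of set C. Of the 258 outside set C, 245 lay in MYC of set D, so that contrast says little of MYCN outside MYC. With the wider peaks of every list the differences in H3K4me3 and H3K4me1 were 42.8 and -30.0 points (Fisher's exact tests, adjusted p = 0.000131 for both). MYCN peaks whose MYC peak was dropped then count as without MYC, so the setting of wider peaks says nothing of MYCN outside MYC. Counting peak centres kept all 28 results on their side, at 0.244 to 1.15 times the main value, and the demand that a peak cover 50% of the shorter one kept 3 of 3. Equal numbers of widest peaks kept 14 of 14, at 0.105 to 1.63 times the main value. The overlaps of MYCN with the 3 marks could not change there, since all 895 MYCN peaks were kept. Stricter thresholds and equal numbers by score, other scores, promoter windows, gene backgrounds and E-box settings were not run, as they need scores, an hg19 annotation or a genome. Unknown depth limits every count of peaks, since a site missing from a list may have been missed at that depth. MYCN in MYC was 98.2% with set D alone and 71.2% with set C alone. Those 2 lists also differ in peak caller and read pairing, so the difference cannot be assigned to depth.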

Other observations

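The regions in this part were chosen after their values were seen. No filter for repeats or poorly mappable sequence was applied, and no IgG list was used. Whether the signal in these regions is binding or background was therefore not tested. The widest MYC regions of set C gathered in few places. Of the 12 widest, 7 lay on chromosome 6 between 26020353 and 27843481, among them a region of 21007 bp from 27773988 to 27794994 with 6 H3K4me3 regions, and 3 lay on chromosome 1. The 2 windows of 1 Mb on chromosome 6 from 26000001 to 28000000 held 140.8 and 86.0 kb of MYC set C, with 49 and 39 H3K4me3 regions and 0 MYCN peaks. The widest MYC region of all, 26879 bp on chromosome 1 from 228757308 to 228784186, overlapped 2 H3K4me3 and 7 H3K4me1 regions, and its neighbour from 228743951 to 228757097 overlapped no H3K4me3 region.

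Wide MYC regions also lay where H3K4me3 was missing, and an effect of repeats or poor mappability there was not tested. The window of 1 Mb on chromosome 4 from 49000001 to 50000000 held 23 regions of MYC set C, 49 peaks of MYC set D and 0 H3K4me3 regions. On chromosome 5 from 49428251 to 49441579 a set C region of 13329 bp overlapped 6 MYC peaks of set D, 1 H3K27ac region and 0 H3K4me3 regions, and on chromosome 4 from 49290718 to 49300915 a region of 10198 bp overlapped 3 MYC peaks of set D and 0 H3K4me3 regions. The widest MYC peak of set D, 3268 bp on chromosome 6 from 58776260 to 58779527, overlapped no region of set C, 1 of H3K27ac and 2 of H3K4me1. Chromosome 19 held 7.46% of the H3K4me3 regions, 7.31% of MYC in set C, 5.69% of MYC in set D and 4.69% of MYCN, but 3.10% of H3K27ac and 3.34% of H3K4me1 regions. Its H3K4me3 regions did not lack these 2 marks. H3K27ac overlapped 63.6% of them and H3K4me1 23.8%, against 66.2% and 14.4% of H3K4me3 regions on all chromosomes.

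MYCN outside MYC comprised 13 peaks, the widest of 356 bp and the narrowest of 150 bp. The 5 of them without H3K4me3 were on chromosome 14 from 105742640 to 105742836, chromosome 6 from 157800952 to 157801125, chromosome 8 from 138795870 to 138796026, chromosome 1 from 204958449 to 204958604 and chromosome 7 from 65020078 to 65020227.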
